A study of Homo sapiens with 6 samples.

How the data were processed

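The series profiled mRNA in SNU449, an established human hepatocellular carcinoma cell line that carried an inducible FOXO1AAA construct in the vector pInducer20. Per the labels' protocols, the cells were cultured for 48 h either without doxycycline (Cont) or with 2 µM doxycycline hydrochloride (Dox), total RNA was extracted from 3 samples of each group, and libraries were made by poly(A) capture and reverse transcription. The submitters' processing notes name FastQC 0.11.7 and the genome build GRCh38. The aligner, the counting tool, the gene annotation and any filter on genes were not given in the sources used here. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The description of the first Cont sample names the same column of the table as that of the second. The columns were matched by title, which leaves the groups as they are and could affect only which Cont library is called replicate 1 and which replicate 2.

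The authors deposited 1 table of 13117 genes by 6 libraries, with gene symbols and no coordinates. It is named as FPKM (fragments per kilobase of transcript and per M mapped reads), but the deposited values are log2 FPKM, running from -8.59 to 13.9, with a small offset added before the logarithm. The design written before the data were examined had assumed linear FPKM. The planned test was kept by taking FPKM as 2 to the power of the deposited log2 value, and a test of the deposited log2 values themselves was added as an alternative after the data were seen. Of the 13117 symbols, 12922 matched exactly 1 gene of GENCODE release 29, which uses GRCh38, and 12892 of these were protein-coding. Coordinates come from that release.

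Depth was not given, so it was estimated from the lowest values. In 307 genes at least 2 libraries shared 1 lowest value, taken as 0 reads. Above that floor, every value tested in these genes, up to 20 reads, lay within 0.05 reads of a whole number of reads, in all 6 libraries. The offset was worth 1.58 to 2.62 reads per library, 2.0 on average. Most of the whole values were even, 58.7% to 80.0% per library, so a fragment often counted as a pair of reads. A scale for read numbers came from gene length: 39.4% of the 302 floor genes with a known length lay within 2% of the length of their longest GENCODE 29 transcript. On that scale the libraries held about 28.4, 41.6 and 33.8 M reads (Cont replicates 1 to 3) and 47.1, 33.5 and 31.3 M reads (Dox replicates 1 to 3), with M for mega. The estimate is rough, because the reads it implies for the listed genes add up to 2.27 to 2.41 times these totals. The relative depths rest on the steps alone. Where every library of a group had 0 reads for a gene, a fold change is given only as a lower bound against 3 reads in each library of that group, which covers counting error only.

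Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation, a mean-variance trend, two-sided p-values and Benjamini-Hochberg adjustment. The 11526 genes with FPKM of at least 1 in at least 3 libraries were tested, and 1591 genes were not. The threshold was an adjusted p under 0.05. Log2 changes are Dox minus Cont on the log2(FPKM + 1) scale, which understates the change of genes with low values. Standard errors (SE) come from limma, and means are given with the SD of the 3 libraries of a group. Fold changes are ratios of mean FPKM. Genes that share sequence with pseudogenes or paralogs, among them ribosomal protein genes and mitochondrial genes with nuclear copies, have uncertain values, since the handling of shared reads is not given in the sources used here.

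A total of 35 gene lists had been written before the data were examined, and 33 of them, with at least 5 tested members, were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 33 lists. The lists of immune cell markers and endothelial markers had too few tested members. Camera with an estimated correlation and limma's fry were run beside it. Genes were named by a rule fixed at the same time: 14 genes of the FOXO, AKT, mTOR, MET and beta-catenin axis whatever their values, the 12 largest rises and 12 largest falls among genes past the threshold with a mean FPKM of at least 1 in the higher group and no overlap between groups, and up to 4 members of each list. Some genes that this rule names are not reported here. Genes named outside this rule are members of the fixed lists that went against the rest of their list or did not pass the test, and members of the families in the closing section, all chosen after their values were seen.

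The alternatives planned before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a filter at FPKM 5, rescaling to TPM, median-of-ratios scaling, quantile normalization, no trend, robust moderation, the replicate number as a block, an adjusted p under 0.01, a further 2-fold minimum, and each library left out in turn. Tests of the deposited log2 values, TPM without the mitochondrially encoded genes, and a 3-read floor for genes without reads were added after the data were seen. The procedure was tested on data simulated from the Cont means and the spread within groups, with 200 changed genes among 11526 in each of 5 runs. It recovered 4% of changes of 0.25 in log2, 46.8% of those of 0.5, 92.4% of those of 1 and 99.2% of those of 2, and 3.66% of its calls were false. In the data 80.4% of the tested genes were called, a far larger share than was simulated. The adjustment depends on that share, so these rates may not hold for the data. A list with a planted shift was found in 100% of 20 runs, with 0 false calls in 620 tests of other lists, but these simulated genes varied independently. Values were prepared and drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.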

Results

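RNA-seq profiles were obtained from 3 libraries of untreated SNU449 hepatocellular carcinoma cells (Cont) and 3 libraries of cells given 2 µM doxycycline for 48 h (Dox). The cells carried FOXO1AAA, a form of the transcription factor FOXO1 in which the sites phosphorylated by the kinase AKT are replaced, under a doxycycline-inducible promoter. The libraries held roughly 28.4 to 47.1 M reads by an estimate from the steps of the lowest values. The table listed 13117 genes as log2 FPKM, and 11526 passed the filter on low values. The comparison asked which transcripts changed when FOXO1AAA was induced. No library received doxycycline without the construct, so in every result below the drug and the induced protein cannot be told apart. The title of the series places the experiment in a study of mTORC2, AKT, FOXO1 and the ubiquitin ligase RNF125 in liver cancer with active c-MET and mutated beta-catenin.

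FOXO1 mRNA (chromosome 13, 40469953 to 40666597, GRCh38) was at FPKM 0.741, 0.776 and 0.889 in the 3 Cont libraries and at 2.87, 3.5 and 2.01 in the 3 Dox libraries. The means were 0.802 ± 0.0777 and 2.79 ± 0.748 (SD, n = 3), a 3.48-fold rise (log2 change 1.06, SE 0.15, limma adjusted p = 9.84e-05). Whether reads of the construct were counted under FOXO1 cannot be told from the table, so this rise does not measure the induction itself. RNF125 (chromosome 18, 32018372 to 32073213) went from 0.496 ± 0.10 to 1.17 ± 0.149 (SD, n = 3), a 2.35-fold rise (log2 change 0.53, SE 0.12, limma adjusted p = 0.00205). Both genes were low, with an estimated 119 to 183 reads for FOXO1 and 90.9 to 114 for RNF125 per Cont library. The RNF125 rise was lost under quantile normalization (log2 change -0.0199, limma adjusted p = 0.883), whereas that of FOXO1 remained (0.73, limma adjusted p = 0.00161). Smaller pseudocounts of 0.1 and 0.01 gave larger log2 changes, 1.65 and 1.76 for FOXO1 and 1.10 and 1.23 for RNF125, the deposited log2 values gave 1.77 and 1.25, and RNF125 was at 0.86 in TPM without mitochondrially encoded genes.

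MET, which encodes the receptor of hepatocyte growth factor, fell from 1194 ± 19.2 to 185 ± 20.4 FPKM (SD, n = 3), a log2 change of -2.69 (limma adjusted p = 3.46e-09). CTNNB1, the gene of beta-catenin, rose from 87.5 ± 3.55 to 134 ± 2.79. RICTOR, the defining subunit of mTORC2, rose from 4.18 ± 0.354 to 16 ± 0.642 (log2 change 1.72, limma adjusted p = 6.04e-08). MLST8, a subunit shared by both mTOR complexes, fell from 68.7 ± 4.69 to 42.0 ± 1.89. FOXO3 rose 2.56-fold and FOXO6 rose 3.44-fold. Smaller differences depended on scaling. FOXO4 rose by 0.40 in log2 but gave 0.02 under quantile normalization (limma adjusted p = 0.908), and MTOR fell by 0.46 but gave -0.19 in TPM without mitochondrially encoded genes (limma adjusted p = 0.0703). AKT1 (-0.34), AKT2 (-0.20) and the mTORC2 subunit MAPKAP1 (-0.20) passed the test as planned, but the call ended under median-of-ratios scaling, quantile normalization and TPM without mitochondrially encoded genes for all 3 genes. Under the last of these AKT1 was at -0.0656 (limma adjusted p = 0.489), and AKT2 and MAPKAP1 turned to 0.0739 and 0.0774. In TPM the calls of AKT2 (limma adjusted p = 0.228) and MAPKAP1 (0.317) ended, and that of MAPKAP1 also ended with the replicate number as a block (0.0519) and without the trend (0.0534). The calls of AKT2 and MAPKAP1 also ended without Cont replicate 1 (AKT2 -0.18, MAPKAP1 -0.21), Cont replicate 2 (-0.18 for each), Dox replicate 1 (-0.20 and -0.21) or Dox replicate 2 (-0.19 and -0.13).

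**Figure D1:**
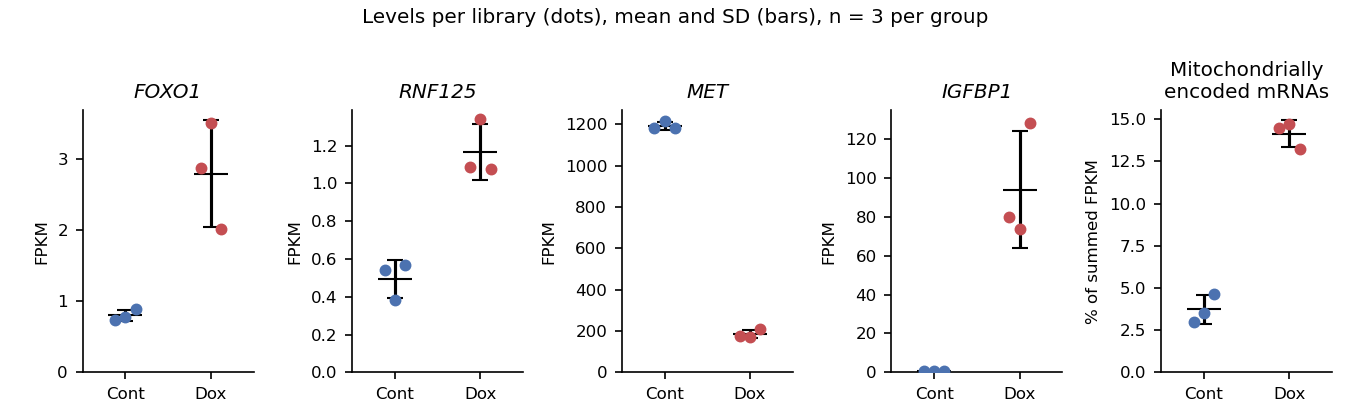
FPKM of FOXO1, RNF125, MET and IGFBP1 and the percentage of summed FPKM from mitochondrially encoded genes in each library; dots are libraries, and bars mark the mean ± SD of the 3 Cont and the 3 Dox libraries. FOXO1 averaged 0.802 in Cont and 2.79 in Dox, and MET 1194 and 185.

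In all, 9265 of the 11526 tested genes changed (80.4%), with 4329 higher and 4936 lower in Dox at a limma adjusted p under 0.05. Of these, 3797 changed at least 2-fold on the log2(FPKM + 1) scale (1882 higher, 1915 lower) and 208 at least 8-fold (117 higher, 91 lower). In 82.1% of the tested genes the 3 Dox and the 3 Cont values did not overlap, where chance gives 10%. The split between directions depended on scaling. Higher genes made up 46.7% of the calls as planned, 47.9% under quantile normalization, 52.8% in TPM, 52.7% with median-of-ratios scaling and 60.2% in TPM without mitochondrially encoded genes, an alternative added after the data were seen. The median change of all tested genes was -0.06 as planned, -0.04 under quantile normalization, 0.06 in TPM, 0.06 with median-of-ratios scaling and 0.22 in TPM without mitochondrially encoded genes, so changes of that size have no fixed sign.

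**Figure D2:**
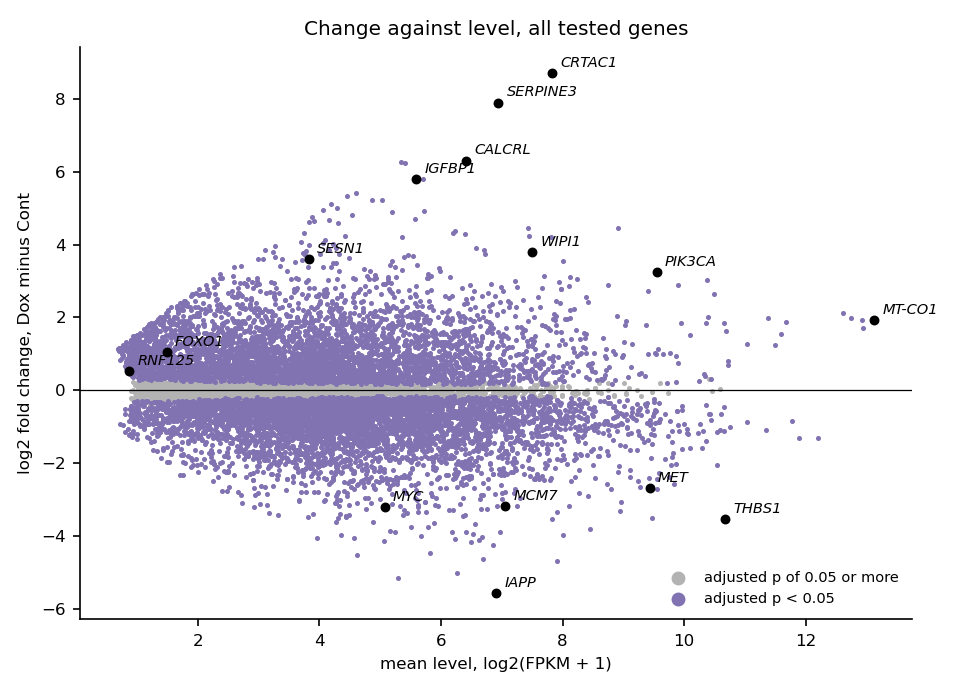
Log2 change (Dox minus Cont, log2(FPKM + 1) scale) against mean expression for the 11526 tested genes; each point is a gene, purple where it passed the test, grey where it did not, and black for genes named beside their points. A total of 4329 genes lie above 0 among those that passed and 4936 below.

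The largest rises included CRTAC1, a gene of an extracellular matrix protein, which went from 0.0329 ± 0.0128 to 450.4 ± 149 FPKM (SD, n = 3; log2 change 8.71, limma adjusted p = 1.42e-09). Its Cont values were 0.0255, 0.0476 and 0.0255 FPKM, and the repeated lowest value stands for 0 reads. The Cont mean is therefore mostly the offset rather than a measured level. SERPINE3 had 0 reads in every Cont library and 243 ± 15.6 FPKM in Dox, at least 6278-fold higher. MOBP and APOD also had 0 reads in every Cont library and were at least 528-fold and at least 406-fold higher in Dox. CALCRL, a receptor subunit for adrenomedullin, rose from 1.13 ± 0.25 to 167 ± 14, and ANGPT2, an angiopoietin, reached 78.7 ± 14.9. IGFBP1, an insulin-repressed gene and a known FOXO target, rose from 0.673 ± 0.189 to 93.9 ± 30.0 (log2 change 5.79, limma adjusted p = 4.18e-09). TTC6 (5.80), TMEM74 (5.41), ATP6V1C2 (5.23), IPCEF1 (5.23) and PXT1 (5.10) completed the 12 largest rises in log2.

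The largest fall in log2 was that of IAPP, the amylin gene, from 234 ± 16.5 to 4.15 ± 1.83 FPKM (SD, n = 3; log2 change -5.57, limma adjusted p = 7.21e-09). By the ratio of mean FPKM, CPA4 fell further, 68.2-fold against 56.3-fold for IAPP. The AP-1 subunit gene FOSL1 fell from 198 ± 17.4 to 7.06 ± 0.779, the adhesion receptor gene CD44 from 218 ± 13.1 to 10.5 ± 0.222, and the receptor tyrosine kinase gene AXL from 186 ± 1.76 to 9.86 ± 1.49. FGB, a fibrinogen chain gene, fell from 170.0 ± 30.4 to 8.57 ± 1.88. Other large falls in log2 were those of CPA4 (-5.16), CLDN2 (-5.03), EREG (-4.53), SPNS2 (-4.45) and SGK2 (-4.15).

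**Figure D3:**
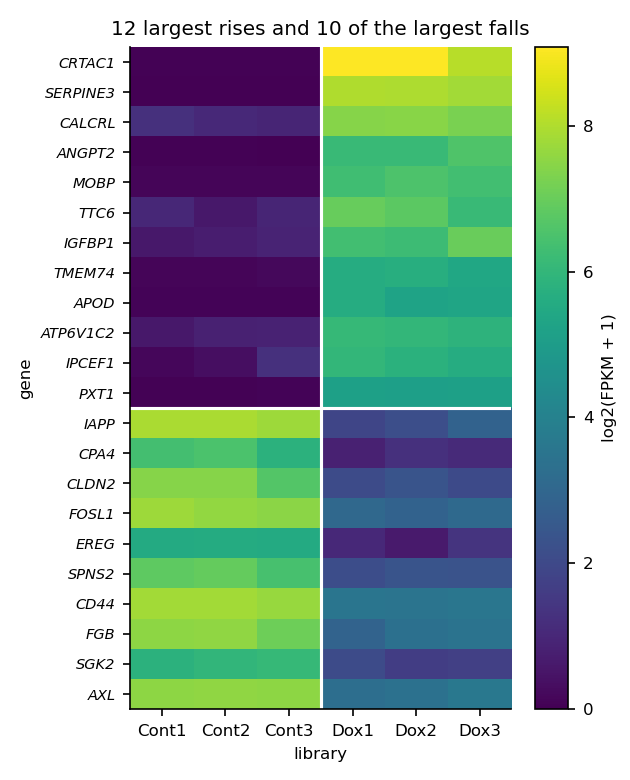
Heat map of log2(FPKM + 1) in the 6 libraries for the 12 largest rises and 10 of the largest falls; colour gives the level, columns are libraries and each line is a gene. CRTAC1 averaged 0.0329 FPKM in Cont, which is mostly the offset, and 450.4 in Dox, and IAPP 234 and 4.15.

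Among the fixed lists, 2 were called higher and 9 lower by camera with a preset correlation, and none of the 11 calls was kept with an estimated correlation. The estimated correlation was -0.01 for the FOXO targets, below the preset 0.01, and 0.104 to 0.818 for the other lists called. A correlation above the preset one therefore does not account for the loss of the FOXO target call. Camera with an estimated correlation takes its p-values on the residual degrees of freedom, which are few with 6 libraries. The preset version takes them from the number of genes. A list could therefore hardly pass with an estimated correlation, and missing that test neither supports nor argues against its call. For each of the 33 lists tested, the counts adjusted over the list alone equalled the counts adjusted over all genes, except for the biliary and progenitor markers. The 11 lists kept their direction and an adjusted p under 0.05 with the preset correlation under TPM, median-of-ratios scaling and quantile normalization, and so did the 10 that could be tested in TPM without mitochondrially encoded genes.

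Direct targets of FOXO factors rose as a list: 22 of 28 measured members rose, 4 fell and 2 did not pass, also when adjusted over the list alone (median log2 change 1.45, camera adjusted p = 4.45e-05; adjusted p = 0.242 with an estimated correlation). SESN1, a sestrin, rose from 1.15 ± 0.388 to 25.1 ± 3.14 FPKM (SD, n = 3), the transcriptional repressor gene BCL6 from 2.22 ± 0.535 to 32.5 ± 3.36, the pro-apoptotic BCL2L11 (BIM) from 25.5 ± 3.15 to 198 ± 7.75 and TNFSF10 (TRAIL) from 6.46 ± 1.73 to 47.6 ± 4.75. GADD45A, GADD45B, TXNIP and BNIP3 fell, by 0.30, 0.50, 0.37 and 0.29 in log2, but none of these 4 falls passed in TPM without mitochondrially encoded genes (limma adjusted p = 0.769, 0.078, 0.182 and 0.849), where 22 members rose and 0 fell. Without Cont replicate 1 or Dox replicate 3, 2 members fell. CDKN1A, the gene of p21, was at 51.8 ± 2.56 and 46.8 ± 6.02 (limma adjusted p = 0.16), and DDIT4 at 2.22 ± 1.03 and 2.46 ± 0.49 (limma adjusted p = 0.547).

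All 13 mRNAs encoded by the mitochondrial genome rose (median log2 change 1.92, camera adjusted p = 4.07e-05; adjusted p = 0.494 with an estimated correlation). MT-ND4 rose from 2770.5 ± 600.2 to 10898 ± 254 FPKM and MT-ATP6 from 2387 ± 499 to 10181 ± 332 (SD, n = 3). These genes took 3.73 ± 0.855% of the summed FPKM in Cont and 14.1 ± 0.80% in Dox. The nuclear genes of the respiratory chain and ATP synthase were not called as a list (6 of 30 rose, 15 fell; camera adjusted p = 0.308) and turned with scaling, to 13 rises and 11 falls in TPM without mitochondrially encoded genes. The list held falls of SDHA (-1.97) and CYC1 (-1.37) and a rise of NDUFS1 (1.44).

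Genes of the cell cycle were lower. Of 30 genes of the G1/S transition and DNA replication, 28 fell and 0 rose (median log2 change -2.33, camera adjusted p = 1.36e-08; adjusted p = 0.458 with an estimated correlation). The replication factor gene MCM10 fell from 35.3 ± 3.48 to 2.20 ± 0.172 FPKM (SD, n = 3), the ribonucleotide reductase gene RRM2 from 38.8 ± 3.98 to 2.66 ± 0.312, and the licensing factor gene CDC6 from 35.9 ± 1.86 to 2.49 ± 0.244. Of 29 genes of G2 and mitosis, 28 fell and 1 rose (median -1.86, camera adjusted p = 2.13e-06; adjusted p = 0.553 with an estimated correlation). AURKB, the Aurora B kinase gene, fell from 74.9 ± 5.32 to 6.23 ± 1.74, whereas the kinetochore motor gene CENPE rose from 11 ± 0.561 to 21.0 ± 1.47. The list of cyclin-dependent kinase inhibitors, pocket proteins and other quiescence genes was not called (6 of 11 rose, 3 fell; camera adjusted p = 0.26). Its members included rises of the kinase inhibitor gene CDKN2C (1.80) and of BTG1 (1.52) and CCNG2 (1.39), and a fall of the pocket protein gene RBL1 (-1.30).

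Lists of ribosome production and heat shock genes were called lower. Of 25 ribosome biogenesis genes, 22 fell and 1, POLR1B, rose (median log2 change -1.74, camera adjusted p = 5.62e-06; adjusted p = 0.458 with an estimated correlation). The nucleolar protein gene NPM1 fell from 921 ± 66.1 to 178 ± 9.25 FPKM (SD, n = 3) and NOLC1 from 140.4 ± 6.76 to 22.6 ± 2.59. Of 33 cytosolic ribosomal protein genes, 31 fell and 0 rose, by less (median -0.73, camera adjusted p = 5.62e-06; adjusted p = 0.575 with an estimated correlation). Their median was -0.43 under quantile normalization and -0.45 in TPM without mitochondrially encoded genes. RPL6 fell from 1215 ± 96.2 to 564 ± 38.9. All 10 measured heat shock genes fell (median -1.78, camera adjusted p = 0.000404; adjusted p = 0.458 with an estimated correlation), with HSP90AB1 from 1021 ± 2.39 to 181 ± 25.7 and the mitochondrial chaperonin gene HSPD1 from 727 ± 41.1 to 123 ± 17.6. Chaperones of the endoplasmic reticulum and unfolded protein response genes were not called (7 of 20 rose, 11 fell; camera adjusted p = 0.81; 8 and 8 in TPM without mitochondrially encoded genes), with a rise of SEL1L (1.73) and a fall of SDF2L1 (-1.46).

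Metabolic lists were lower in glycolysis and fatty acid synthesis. Of 18 glycolysis genes, 17 fell and 1, the lactate carrier gene SLC16A1, rose (median log2 change -1.30, camera adjusted p = 0.000226; adjusted p = 0.458 with an estimated correlation). ENO1, an enolase, fell from 1567 ± 46.6 to 264 ± 35.8 FPKM and LDHA, a lactate dehydrogenase, from 619 ± 7.72 to 117 ± 23.4 (SD, n = 3). Of 16 genes of fatty acid synthesis, 13 fell and 2 rose (median -1.41, camera adjusted p = 0.00191; adjusted p = 0.458 with an estimated correlation), with 0 or 1 rise when any 1 library was left out. Among the falls were SCD, the stearoyl-CoA desaturase gene, from 150.3 ± 20.8 to 13.0 ± 3.58 and the regulator gene SREBF1 from 96.4 ± 3.17 to 20.4 ± 3.19. Of 16 genes raised by NRF2, 13 fell and 3 rose (median -1.43, camera adjusted p = 0.0123; adjusted p = 0.463 with an estimated correlation). The transketolase gene TKT fell from 417 ± 25.1 to 35.1 ± 3.65 and the quinone reductase gene NQO1 from 330.4 ± 15.4 to 60.7 ± 4.64, while the heme oxygenase gene HMOX1 (1.37), the glutathione synthesis gene GCLC (1.99) and the cystine carrier gene SLC7A11 (2.36) rose. Of 19 genes raised by TGF-beta, 15 fell and 2, CCN2 and JUNB, rose (median -1.21, camera adjusted p = 0.00326; adjusted p = 0.494 with an estimated correlation), with THBS1, the thrombospondin 1 gene, from 3002 ± 111 to 259 ± 31.8. In TPM without mitochondrially encoded genes, 14 members of the TGF-beta list fell and 4 rose.

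**Figure D4:**
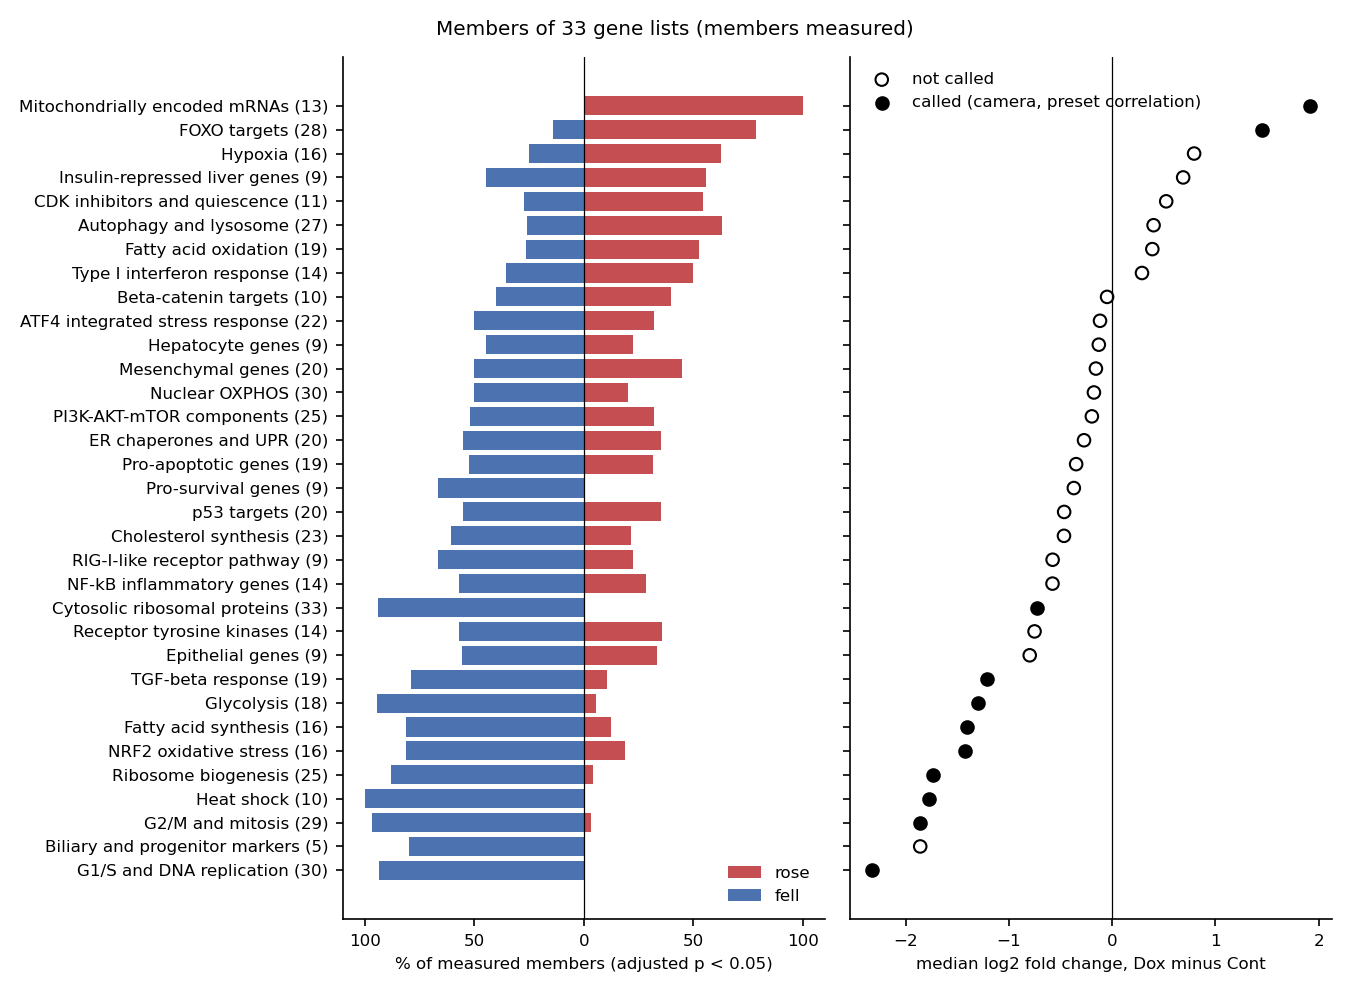
Percentage of measured members that rose or fell (bars) and median log2 change (points) for the 33 tested lists; filled points mark the 11 lists called by camera with a preset correlation. The FOXO target list had a median of 1.45 and the G1/S list one of -2.33.

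The other lists were not called, and for several of them the balance of rises and falls depended on scaling. Insulin-repressed liver genes had 5 rises and 4 falls among 9 (camera adjusted p = 0.803). Without any 1 Dox replicate there were 3 rises and 4 falls, and the median log2 change went from 0.69 to -1.29, -1.12 and -1.10 without replicates 1, 2 and 3, because IGFBP1 and the glucose-6-phosphatase gene then missed the filter of 3 libraries. IGFBP1 (5.79) rose, TRIB1 (-1.76) and ANGPTL4 (-1.58) fell, and the glucose-6-phosphatase gene, with 0 reads in every Cont library, was at least 20.7-fold higher. Components of the PI3K, AKT and mTOR complexes had 8 rises and 13 falls among 25 (camera adjusted p = 0.903), but 9 and 9 with median-of-ratios scaling and 9 and 7 in TPM without mitochondrially encoded genes. PIK3CA, a catalytic subunit of PI3K, rose from 142 ± 13.8 to 1354 ± 87.8 FPKM (SD, n = 3), and SGK3 rose (2.89), while the mTORC2-associated PRR5L (-3.18) and EIF4EBP1 (-2.15) fell. Of 14 receptor tyrosine kinases, 5 rose and 8 fell (camera adjusted p = 0.26), with falls of FGFR1 (-3.26) and EPHA2 (-2.83) beside those of AXL and MET. Beta-catenin targets had 4 rises and 4 falls among 10 (camera adjusted p = 0.903), with falls of MYC from 59.8 ± 13.4 to 5.47 ± 0.751 and of CCND1 from 117 ± 7.59 to 17.3 ± 1.65, and a rise of TBX3 (1.73). The PI3K list had a median of -0.20 and a mean of 0.08 in log2, with a downward camera statistic.

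Pro-apoptotic genes had 6 rises and 10 falls among 19 (camera adjusted p = 0.903; median log2 change -0.35, mean 0.24, downward statistic), but 8 and 7 in TPM without mitochondrially encoded genes, with rises of APAF1 (2.42) and CASP9 (1.59) beside BCL2L11 and TNFSF10. Pro-survival genes had 0 rises and 6 falls among 9 (camera adjusted p = 0.102), but 2 and 5 under quantile normalization and 3 and 4 in TPM without mitochondrially encoded genes. The falls included BCL2L1 (BCL-XL) from 83.0 ± 5.37 to 9.84 ± 0.317 FPKM (SD, n = 3) and BIRC5 (-1.86). Targets of p53 had 7 rises and 11 falls among 20 (camera adjusted p = 0.803; median -0.47, mean 0.07, downward statistic), with rises of TP53INP1 (2.39) and RRM2B (1.95) and a fall of AEN (-2.10). Autophagy and lysosome genes had 17 rises and 7 falls among 27 (camera adjusted p = 0.0635; adjusted p = 0.458 with an estimated correlation), with WIPI1 rising from 23.3 ± 3.34 to 337 ± 48.7, and with ULK2 (1.67) and GABARAPL1 (1.35) also up. With the preset correlation, that list passed the test without any 1 of the Dox replicates (camera adjusted p = 0.0272, 0.0258 and 0.0281 without replicates 1, 2 and 3) and under quantile normalization (camera adjusted p = 0.0319). Hypoxia genes outside glycolysis had 10 rises and 4 falls among 16 (camera adjusted p = 0.057; adjusted p = 0.458 with an estimated correlation), with rises of PDK1 (2.85) and MXI1 (1.92) and a fall of VEGFA (-2.52). With the preset correlation, they passed without any 1 of the Dox replicates (camera adjusted p = 0.0304, 0.0258 and 0.0321) and without Cont replicate 3 (camera adjusted p = 0.0343). Without a Dox replicate, genes that reached FPKM 1 only in Dox missed the filter of 3 libraries. The tested genes then numbered 10961 to 10969 and their median change was -0.12, against 11526 and -0.06 as planned. Camera compares a list with the other genes, so the passes of both lists without a Dox replicate are not separated from that shift.

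Genes raised by ATF4 had 7 rises and 11 falls among 22 (camera adjusted p = 0.614), but 10 and 10 in TPM without mitochondrially encoded genes, with falls of the amino acid carrier genes SLC7A5 (-3.25) and SLC3A2 (-2.37) and a rise of NUPR1 (2.20). Cholesterol synthesis had 5 rises and 14 falls among 23 (camera adjusted p = 0.154), or 8 and 11 in TPM without mitochondrially encoded genes, including EBP (-1.87), against a rise of TM7SF2 (2.04). Fatty acid oxidation had 10 rises and 5 falls among 19 (camera adjusted p = 0.308), with PDK4 (1.12), HADHB (1.06) and PPARA (1.06) up. Its counts were 10 and 2 in TPM without mitochondrially encoded genes and 10 and 7 without Cont replicate 3. The type I interferon response had 7 rises and 5 falls among 14 (camera adjusted p = 0.803), but 4 rises without Dox replicate 3 and 3 falls without any 1 Cont replicate, with STAT2 (1.49) up and IFIT1 (-1.26) down. The RIG-I pathway had 2 rises and 6 falls among 9 (camera adjusted p = 0.25), with TRIM25 from 43.1 ± 2.95 to 15.7 ± 0.343 FPKM (SD, n = 3) and IRF3 (-0.85). That list holds reported substrates of RNF125, but TRIM25 and IRF3 are not named here as such substrates. Inflammatory genes of NF-kB had 4 rises and 8 falls among 14 (camera adjusted p = 0.531), with CCL2 (-2.84) and ICAM1 (-1.18) down and TRAF1 (1.47) up.

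Mesenchymal genes had 9 rises and 10 falls among 20 (camera adjusted p = 0.903), but 11 and 9 in TPM without mitochondrially encoded genes. COL3A1 rose from 5.93 ± 0.919 to 142 ± 15.6 FPKM (SD, n = 3) and FN1 rose (1.88), while COL6A3 (-2.72) and COL1A2 (-2.17) fell. Epithelial genes had 3 rises and 5 falls among 9 (camera adjusted p = 0.565), but 6 and 6 in TPM without mitochondrially encoded genes, where more members passed the filter, with CLDN4 up (2.96) and CLDN1 (-3.01) and KRT18 (-2.43) down. Hepatocyte genes had 2 rises (1 without any 1 Dox replicate) and 4 falls among 9 (camera adjusted p = 0.81), but 5 and 4 in TPM and 6 and 4 in TPM without mitochondrially encoded genes, with the pioneer factor gene FOXA1 up (2.81) and the fibrinogen genes FGB (-4.16), FGG (-1.69) and FGA (-1.65) down. Biliary and progenitor markers had 0 rises and 4 falls among 5, and 1 rise and 4 falls adjusted over the list alone (camera adjusted p = 0.0932), or 2 and 5 in TPM, where more members passed the filter, with SPP1 from 885 ± 28.3 to 106 ± 23.2 and CD24 from 438 ± 75 to 42.0 ± 2.5. Of the 21 immune cell markers 1 was tested, CD14, at 2.13 ± 0.349 in Cont and 2.30 ± 0.065 in Dox (limma adjusted p = 0.514), and of the 12 endothelial markers 0 were.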

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

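Tests of the deposited log2 values, of TPM without mitochondrially encoded genes and of a 3-read floor were chosen after the results were seen, and the other alternatives before. The counts of changed genes stayed within 1.5 times the planned ones except with a further 2-fold minimum (3797 genes, 1882 higher, 1915 lower, fewer by construction), and with 1 library left out they were 8319 to 9118 (3589 to 4310 higher, 4539 to 4860 lower). Of the 9265 calls, 8784 were kept in direction in TPM and 8487 under quantile normalization, where 3 were called the other way, and 8124 of 9252 in TPM without mitochondrially encoded genes. FOXO1 kept its call under every alternative that tested it, at 0.73 (quantile normalization) to 1.77 (deposited log2 values) and at 1.03 to 1.09 with 1 Cont library left out. RNF125 kept its call at 0.48 to 1.25 (limma adjusted p = 0.000417 to 0.0139; 0.48 to 0.57 with 1 Cont library left out) except under quantile normalization (-0.0199, limma adjusted p = 0.883). Without 1 Dox library, or at FPKM 5, neither gene passed the filter. AKT2 (0.0739) and MAPKAP1 (0.0774) reversed in TPM without mitochondrially encoded genes. Lists called higher numbered 4 at a filter of FPKM 5, 1 in TPM without mitochondrially encoded genes, whose own list was then not tested, and 2 to 4 with 1 library left out, while 9 to 9 were lower. Camera with an estimated correlation called 0 lists higher and 0 lower, with 1 of the 33, the FOXO targets, at an unadjusted p under 0.05. By contrast fry, which does not compare a list with other genes, gave 9 higher and 19 lower. The cause of these differences was not tested beyond the constructions named.

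Cont and Dox libraries of the same number did not deviate together (correlations across genes 0.037, -0.005 and 0.079). With the replicate number as a block, 9272 genes changed (4335 higher, 4937 lower), and 9144 of the 9265 calls were kept in direction. Depth limits the lowest genes. Under a 3-read floor, 219 genes lacked reads in Cont alone and 9 in Dox alone, against 156 and 7 at 0 reads.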

Other observations

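The 24 gene families described first were chosen after the values were seen, and the definitions of several were corrected once after a first look. The comparison of genes lost with genes gained was also chosen after its result was seen. The requirement that a result pass its bound by more than a bootstrap standard error was added after the values were seen too. The other tests were fixed before their results were seen.

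Of the 24 families, chosen after the values were seen, 7 were called lower in Dox with the preset correlation, and none with an estimated one (adjusted p = 0.696 for each). Their medians stayed below 0 under TPM, median-of-ratios scaling, quantile normalization and TPM without mitochondrially encoded genes. Of 75 genes of the mitochondrial ribosome, 59 fell and 10 rose (median log2 change -0.70, camera adjusted p = 5.53e-05 over the 24 families), with MRPL12 at -2.07, while the mRNAs of the mitochondrial genome rose. Of 54 splicing factor genes, 42 fell and 5 rose (camera adjusted p = 4.71e-05), with HNRNPAB at -2.31. Translation initiation factors fell in 34 of 44 (camera adjusted p = 0.000639), aminoacyl-tRNA synthetases in 23 of 32 (0.00268), proteasome subunits in 25 of 34 (0.00314), nucleoporins in 18 of 22 and subunits of the chaperonin CCT in 8 of 9 (both 0.00715).

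Called higher with the preset correlation were 2 families, and neither was with an estimated one (adjusted p = 0.696 for both). Their medians stayed above 0 under the same 4 scalings. Of 19 axonemal dynein and CFAP genes, 14 rose and 2 fell (camera adjusted p = 0.00715), with DNAH7 at 2.90 and CFAP70 at 2.68 in log2. Of 15 intraflagellar transport genes, 11 rose and 1 fell (camera adjusted p = 0.0188), with IFT27 at 1.79. Change also followed expression level, with a median of 0.29 in the lowest of 5 equal bins of tested genes and -0.33 in the highest. The calls of lists and families compare members with other genes of any level, so their p-values are not adjusted for this trend. List medians such as -2.33 (G1/S) and 1.45 (FOXO targets) lie far outside these bin medians, which argues against the trend as their whole cause. Medians nearer to them, such as -0.73 (cytosolic ribosomal proteins) and 0.49 (axonemal dyneins and CFAP), are not separated from it.

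The rise of the 13 mitochondrially encoded mRNAs had 3 explanations weighed against it. The authors' scaling as its whole cause is argued against. The lowest median change over 3 other scalings was 1.30 (quantile normalization, bootstrap SE 0.251). The share of summed FPKM within a library needs no scaling between libraries. The 13 genes had an estimated correlation of 0.818, so they are not independent, and this SE may understate the spread between libraries. All these measures are relative, so they cannot tell more mitochondrial mRNA per cell from less nuclear mRNA per cell. Loss of cytoplasmic RNA from damaged cells stays open: abundant nuclear classes would have fallen alike, and their list medians lay 1.12 apart (cytosolic ribosomal proteins -0.73, nuclear respiratory chain -0.18, glycolysis -1.30), past the bound of 1 but by less than its bootstrap SE of 0.378. Doxycycline, which inhibits mitochondrial translation, cannot be told apart from the induced protein, because 0 libraries received the drug without the construct. A response to FOXO1AAA is a further possible source, as a hypothesis that these libraries leave untested.

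A total of 156 genes had 0 reads in every Cont library and reads in every Dox library, 50 of them at a Dox FPKM of at least 1, against 7 the other way round. Any filter that the authors applied to genes is not known. Such a filter decides which genes without reads in a group are listed, so it could shift this balance. An even background of genomic DNA or unspliced RNA as the whole cause is argued against, since the 90th percentile of their Dox FPKM was 22.21 times the 10th. That ratio does not speak to an uneven background. Nor does it speak to a background behind part of these genes, whose median Dox FPKM was 0.50. Another cell line in the Dox libraries would be likely to lose about as many genes as it gains, and the ratio of losses to gains was 0.0449, but that bound was set with the counts known and expression values hold no genotype, so it stays open. Cells of another type mixed into the Dox cultures also stay open: 121 genes with a Cont FPKM of at least 10 fell more than 8-fold, which met the bound of 100 written in advance, but that bound was wrong, since a small share dilutes little and can coexist with falls of other origin. A share of 3.61% could bring the highest of these genes if it were as abundant in those cells as the highest nuclear gene here.

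Dox replicate 3 lay closer to the Cont libraries (Pearson correlation across genes 0.889 to 0.894) than Dox replicates 1 and 2 did (0.874 to 0.879), and its changes had a slope of 0.961 on the mean change, against 1.017 and 1.022 for the others. Uninduced cells in that library as the whole cause are argued against, within the limits given below. Such cells would give 1 share from all genes, but the share was 0.134 from 245 genes at least 8-fold higher in FPKM in Dox replicates 1 and 2 than in Cont, with no pseudocount, and 0.014 from 161 genes at least 8-fold lower, all at an FPKM of at least 5 in the higher group, a difference of 0.1195 (bootstrap SE 0.0137). Across genes the quartiles were 0.0193 and 0.2301 for the first share and -0.0015 and 0.0332 for the second. Both shares rest on 1 library, so the SE holds no spread between libraries. Picking genes by their values in Dox replicates 1 and 2 can by itself raise the first share, and by how much was not tested. A weaker induction may remain, but it was not tested: FOXO1 was at 2.01 FPKM there against 2.87 and 3.5, and whether reads of the construct were counted under FOXO1 is not known.

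The 6 libraries form 10 splits into groups of 3, too few for a share under 0.05. The real split gave 9265 changed genes and the highest of the others 0 by limma (9410 and at most 30 at an unadjusted p under 0.05). Only 1 of the 10 splits, the real one itself, gave as many. For lists called by camera with a preset correlation, the real split gave 11 and the highest of the others 14. Of the 10 splits, 4 gave at least as many lists as the real one, the real one included. Each other split mixes Cont and Dox libraries in both of its groups. Part of the difference between Dox and Cont stays in its contrast, and the rest widens the spread within its groups. The other splits therefore do not show how many genes or lists would be called without a Dox effect.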
